A study of Mus musculus with 4 samples.

How the data were processed

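Single nuclei were profiled from the dorsal vagal complex of Hsd11b2-IRES-Cre mice of both sexes, which carry Cre recombinase in cells that express Hsd11b2, the enzyme that inactivates corticosterone and so leaves the mineralocorticoid receptor open to aldosterone. A Cre-dependent virus had marked the nuclei of these cells in the nucleus of the solitary tract with mCherry, and flow sorting enriched for marked nuclei. Mice received vehicle or aldosterone at 250 ng per hour from osmotic pumps for 24 h. Per the labels' protocols, tissue was pooled by treatment before nuclei were isolated, libraries were made with 10x Genomics GEM-X chemistry, and replicate 2 was sequenced on an Illumina NovaSeq instrument and replicate 3 on an Element AVITI instrument. The number of mice per pool is not given in the sources used here. The replicates are separate libraries by their labels. The series has 4 libraries, 2 per treatment. The matrix of aldosterone replicate 2, for which 71244 barcodes are listed, was not analysed here, which left 1 aldosterone library and 2 vehicle libraries. P-values thus rest on the spread between the 2 vehicle pools, which also differ in instrument. No spread between aldosterone pools was measured.

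The deposited matrices hold raw UMI counts per gene and barcode, per the file headers, and were made by the authors with Cell Ranger on mm10, per the submitters' processing notes. The Cell Ranger version is not given in the sources used here. The smallest barcode total was 500 UMIs in each of the 3 matrices. Of the 32285 gene identifiers in the files, 32158 (99.6%) matched GENCODE M21 on mm10, from which coordinates were taken. The 2 vehicle libraries were checked for being 1 library deposited 2 times, and they were not, with a chi-square per gene of 4.87 over 10988 genes with at least 50 counts in HSD2-like neurons and of 38.8 over 18934 genes in all nuclei, where cell composition enters too.

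Barcodes with at least 500 detected genes and at most 5% mitochondrial UMIs were kept. Scrublet in scanpy 1.11.5 was run per library on 30 principal components. Its automatic threshold marked 4 barcodes (0.0496%) in vehicle replicate 2, 1 (0.0152%) in vehicle replicate 3 and 3 (0.0333%) in aldosterone replicate 3, so it had not worked. The highest scores were removed instead, up to an expected rate of 0.4% per 1000 nuclei, which took out 298 (3.69%), 212 (3.23%) and 335 (3.72%) barcodes in the same order. Counts were scaled to 10000 per nucleus and log-transformed, 3000 variable genes without the sex-linked list gave 40 principal components, and 20 nearest neighbours were clustered by the Leiden method at resolution 1.0, with leidenalg 0.10.2. Neurons were clustered again in the same way. Clusters were named from 19 marker sets fixed in advance. A marker counted at 2 times the mean level of the other clusters and in 5% of nuclei, and a name needed 3 markers, which for HSD2-like clusters had to include Hsd11b2 and Nr3c2. A neuron cluster without a name by this rule took the glutamatergic or the GABAergic and glycinergic name if its summed level of that transmitter side's genes was over 3 times that of the other side and 3 of the name's markers stood at 2 times the mean of the clusters of the other side. Several GABAergic or glycinergic clusters were named in this way only.

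The thresholds of the naming rule and those that kept clusters out of the classes were set after the data were seen, while the marker sets were not. Unnamed clusters held 34.1%, 40.2% and 45.5% of nuclei in vehicle replicate 2, vehicle replicate 3 and aldosterone replicate 3. Neuron clusters led by markers of other cell types or by mitochondrial RNA, or of low depth, held 2.84%, 1.89% and 1.90%. A cluster with over 90% of its nuclei in 1 library held 2.21%, 0.0787% and 0.0115%. The names were rebuilt here, so class sizes can differ from those of the study. Endothelial nuclei, at 14 in vehicle replicate 3, fell under the minimum of 20 nuclei per library and were not tested.

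UMI counts were summed over the nuclei of a class in each library, and the sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F test, robust off, two-sided) with Benjamini-Hochberg adjustment over the genes of a class at 0.05. Values in CPM are these sums scaled by TMM library sizes, and levels of marker genes outside the test are plain CPM. All adjusted p-values of genes come from this test unless another is named. The contrast leaves 1 residual degree of freedom, so the spread comes from the vehicle libraries and the lone aldosterone library is assumed to vary like them. In HSD2-like neurons, oligodendrocyte precursors, leptomeningeal cells and leukocytes the prior degrees of freedom were estimated as infinite, so the spread of a single gene between the vehicle libraries did not enter its test. In other neurons they were 9.24. For this reason the log2 fold change within replicate 3, where both treatments ran on the same instrument, stands beside most named genes, and the vehicle values beside some. Of 26 named genes that passed in HSD2-like neurons, 23 lay further from both vehicle libraries than these from each other, and Taco1, Cntnap5b and Zbtb16 did not. In other classes 63 of 68 did, and Taco1 in 2 classes, Lrrtm4 in astrocytes, Myo1e in oligodendrocyte precursors and Grik1 in ependymal cells did not. The difference between classes was tested as the class by treatment term in a model of HSD2-like and other neurons with library as a block.

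The marker sets, the gene lists, the rules for named genes and all alternatives not given as added were fixed before the data were examined. The 19 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside an estimated correlation, with adjustment over the lists of a class. With an estimated correlation the test rests on 1 residual degree of freedom and can hardly pass a list. Its p-values therefore do not decide whether a list moved. The median log2 fold change within replicate 3 was set against 10000 random lists matched on mean expression. These percentiles and camera at the preset correlation weigh a list against the spread across genes, not between aldosterone pools. A difference of the 1 aldosterone pool that the genes of a list share would thus pass too. Named genes in HSD2-like neurons were the 12 highest and 12 lowest by log2 fold change among genes past the threshold, outside the range of both vehicle libraries and at a mean of 20 CPM or more, plus genes fixed in advance. In other classes up to 5 genes per direction were named by the same rule. For the difference between classes the rule took the 6 largest values past the threshold, which were all genes with a treatment group at 0 UMIs. Their values are given as bounds with that group set to 3 counts, and 6 further genes were chosen after this was seen, by adding the level and range conditions of the first rule. Clone names, Gm names and mitochondrial genes were counted and not named, and some other genes taken by these rules or lists are not reported here.

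The test was checked on simulated counts with 200 changed genes. For HSD2-like neurons it recovered 144 (72%) of genes changed by a simulated fold of 2, with 27 false calls (15.8% of calls, 13581 genes run), and 199 of genes changed by a fold of 4, with 30 false calls (13.1%, 13572 genes). With no changed gene it made 5 calls (13577 genes). In other neurons it recovered 197 at a fold of 2 with 49 false calls (19.9%, 19221 genes) and 200 at a fold of 4 with 57 (22.2%, 19217 genes). In microglia it recovered 17 at a fold of 2 with 15 false calls (46.9%, 10097 genes) and 130 at a fold of 4 with 4 (2.99%, 10128 genes). The difference test recovered 97 at a fold of 2 with 6 false calls (5.83%, 9906 genes). Unlike the others, its simulation gave all genes the same dispersion and took only genes well counted in HSD2-like neurons. Its share of false calls is therefore not comparable with theirs and does not describe the test on all genes. Falsely called genes thus made up more than 5% of calls in most of these simulations. No call was made in microglia without changed genes (10140 genes), and 5 were made in other neurons (19249 genes). All simulated libraries of a class shared the same means apart from depth and the changed genes. No difference between pools or instruments entered beyond independent spread per gene, so false calls from such differences are not covered.

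Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, minimums of 1000 and 300 genes per nucleus, Scrublet calls kept in, sums thinned to equal totals, other clustering resolutions, nuclei with an Hsd11b2 UMI only, and each vehicle library left out. Those added after the data were seen were a robust prior, limma voom, a clustering without the HSD2 markers and the called genes, the deeper HSD2-like cluster alone, HSD2-like nuclei drawn so that each library had the same numbers per bin of 0.5 log2 UMIs, genes beyond the gap between vehicle libraries, and GABAergic neurons as the comparison class. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error only. The submitters' library preparation of the aldosterone pool cannot be separated from its treatment, since 1 aldosterone library entered.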

Results

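Aldosterone is an adrenal hormone that drives sodium retention and sodium appetite, and the neurons of the nucleus of the solitary tract that express Hsd11b2 (HSD2 neurons) are a brain target for it. The comparison of vehicle with 24 h of aldosterone asks which transcripts change in these neurons and in the cells around them. The matrices held 25458 barcodes and 101153859 UMIs in vehicle replicate 2, 19544 barcodes and 68588650 UMIs in vehicle replicate 3, and 33339 barcodes and 89658488 UMIs in aldosterone replicate 3. After filtering, 7772, 6350 and 8665 nuclei remained, with a median of 4060, 2213 and 2077 UMIs per nucleus.

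Clustering gave 41 clusters of all nuclei and 32 of neurons. The HSD2-like class joined 2 neuron clusters that carried Hsd11b2, the mineralocorticoid receptor gene Nr3c2 and the angiotensin receptor gene Agtr1a. Nr3c2 stood at 2649 and 3087 CPM in the vehicle libraries against 415 and 378 CPM in other neurons, and Slc17a6, the vesicular glutamate transporter, at 171 and 170 CPM. The class held 177 nuclei (2.28% of retained nuclei, interval 1.96 to 2.63%) in vehicle replicate 2, 168 (2.65%, 2.27 to 3.07%) in vehicle replicate 3 and 179 (2.07%, 1.78 to 2.39%) in aldosterone replicate 3. These shares depend on the sort for mCherry and were not tested. The deeper cluster held 157, 113 and 121 of these nuclei in the same order, and the shallower cluster 20, 55 and 58. The HSD2-like sums were 6223484, 5556340 and 3830757 UMIs, and the median nucleus had 37175, 37338 and 20383 UMIs.

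In HSD2-like neurons, Sv2c, which encodes a synaptic vesicle glycoprotein, rose from 24.4 ± 6.57 CPM (SD, n = 2) with vehicle to 104 CPM with aldosterone, a log2 fold change of 2.11 (SE 0.17, adjusted p = 6.89e-32) and of 1.83 within replicate 3. Fkbp5, a co-chaperone of steroid receptors and a known glucocorticoid and mineralocorticoid target, rose from 199 and 269 CPM to 460 CPM (log2 0.98, SE 0.11, adjusted p = 1.14e-14, 0.77 within replicate 3). Hsd11b2 itself rose from 15.7 and 16.8 CPM to 44.6 CPM (log2 1.46, SE 0.22, adjusted p = 4e-09, 1.39 within replicate 3). The adhesion gene Cntn5 fell from 488 and 426 CPM to 179 CPM (log2 -1.35, SE 0.12, adjusted p = 5.57e-24, -1.24 within replicate 3). Dgkb, a diacylglycerol kinase, fell from 240 and 303 CPM to 107 CPM (log2 -1.34, SE 0.14, adjusted p = 1.05e-19, -1.50 within replicate 3). On mm10, Sv2c (ENSMUSG00000051111) lies on chromosome 13 from 95954594 to 96132577, Fkbp5 (ENSMUSG00000024222) on chromosome 17 from 28399094 to 28517527, Hsd11b2 (ENSMUSG00000031891) on chromosome 8 from 105518755 to 105523988, Cntn5 (ENSMUSG00000039488) on chromosome 9 from 9660891 to 10904775, and Dgkb (ENSMUSG00000036095) on chromosome 12 from 37817726 to 38634239. All 5 are protein-coding genes.

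Of 14002 genes tested in HSD2-like neurons, 516 passed an adjusted p of 0.05, 242 higher and 274 lower with aldosterone, with median log2 fold changes of 0.80 and -0.74. Of these, 86 higher and 81 lower genes changed by at least a factor of 2. An unadjusted p under 0.05 was reached by 1854 genes. The direction was the same against each vehicle library for 510 of the 516, and 436 (209 higher, 227 lower) lay further from both vehicle libraries than these lay from each other. The DESeq2 Wald test called 74 genes, limma voom 276, the deeper HSD2-like cluster alone 291, neurons clustered at resolution 2.0 330, sums with Scrublet calls kept in 321, and nuclei matched on UMIs, at 78 per library, 239. Hsd11b2 was among the markers that named the class, and Fkbp5, Zbtb16 and Nr3c2 were among the genes that set its clusters apart. In a clustering without these markers and without the called genes, chosen after the data were seen, the log2 fold changes were 1.49 for Hsd11b2 and 1.03 for Fkbp5. The HSD2-like clusters of that run were still picked by Hsd11b2 and Nr3c2, so the choice was not free of these genes. They held 157, 122 and 118 nuclei, against 157, 113 and 121 in the deeper cluster. The DESeq2 Wald test did not call Fkbp5 (adjusted p = 0.236) and gave no adjusted p for Hsd11b2. In nuclei with an Hsd11b2 UMI only, Dock10 stood at log2 0.82 (adjusted p = 0.426), Cd44 at -0.32 (adjusted p = 0.811) and Nr3c1 at -0.83 (adjusted p = 0.00688).

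Among the other large increases in HSD2-like neurons, Synm, an intermediate filament protein, rose by log2 1.91 (1.49 within replicate 3, adjusted p = 1e-13), Dock10, an exchange factor for small GTPases, by 1.63 (1.58, adjusted p = 3.05e-09), and Arhgef26, another such factor, by 1.41 (1.37, adjusted p = 5.26e-09). Col25a1, a transmembrane collagen, rose by 1.60 (1.89 within replicate 3, adjusted p = 5.14e-13), Pappa, a protease of insulin-like growth factor binding proteins, by 1.46 (1.59, adjusted p = 1.94e-16), and Crtac1 from 71.3 and 55.9 CPM to 166 CPM (log2 1.38, 1.57 within replicate 3, adjusted p = 1.26e-19). Plxdc2 rose by 1.34 (1.46 within replicate 3, adjusted p = 2.62e-11), the granule protein gene Scg2 by 1.31 (0.97, adjusted p = 1.53e-11), Trhde, an enzyme that degrades thyrotropin-releasing hormone, by 1.31 (0.98, adjusted p = 2.4e-13), and the kinase gene Map3k19 by 1.47 (1.43, adjusted p = 1.68e-09). Scg2 also led a shallow unnamed cluster, together with Penk and Hspa8, that held 609, 457 and 1330 nuclei of vehicle replicate 2, vehicle replicate 3 and aldosterone replicate 3.

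Among the other large decreases, Cntn6, a contactin like Cntn5, fell by log2 1.22 on the same scale, from 353 and 280 CPM to 136 CPM (adjusted p = 1.14e-17, -1.04 within replicate 3). Cntnap5b had a log2 fold change of -1.17 (-0.65 within replicate 3, adjusted p = 1.72e-07) from 80.1 and 43.4 CPM, and Cd44, a hyaluronan receptor, of -1.19 (-1.36, adjusted p = 4.25e-06). Grin3a, an NMDA receptor subunit, fell by log2 1.23 (-1.01 within replicate 3, adjusted p = 3.03e-10), Pde1a, a calmodulin-dependent phosphodiesterase, by 1.17 (-0.89, adjusted p = 2.04e-16) and Hs3st5, a heparan sulfate sulfotransferase, by 1.24 (-1.17, adjusted p = 5.18e-14). Ighm, the constant region of the immunoglobulin mu chain, fell from 87.4 and 61.7 CPM to 25.8 CPM (log2 -1.53, -1.25 within replicate 3, adjusted p = 1.86e-13). It was also among the leading genes of an unnamed cluster, with Igha and Jchain. That cluster held 50, 23 and 28 nuclei of vehicle replicate 2, vehicle replicate 3 and aldosterone replicate 3. The transcription factor gene Ebf1 had a log2 fold change of -1.48 (-1.35 within replicate 3, adjusted p = 7.28e-10) and Mei4 of -1.44 (-1.40, adjusted p = 8.94e-08). Taco1, a mitochondrial translation factor, was called at log2 -1.45 (-2.12 within replicate 3, adjusted p = 2.57e-24), but its vehicle values of 139 and 534 CPM lay further apart than vehicle replicate 2 lay from the aldosterone library at 123 CPM. Taco1 lost its call with Scrublet calls kept in (adjusted p = 0.0507), at resolution 2.0 (log2 -0.64, adjusted p = 0.0983) and in the deeper cluster alone (-0.67, adjusted p = 0.121), and it led an unnamed cluster of 5634 nuclei. By DESeq2 the adjusted p was 1 for Taco1, 0.223 for Pde1a and 0.927 for Cntnap5b, and none was given for Synm, Dock10, Col25a1, Map3k19, Arhgef26, Mei4 and Cd44.

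**Figure D1:**
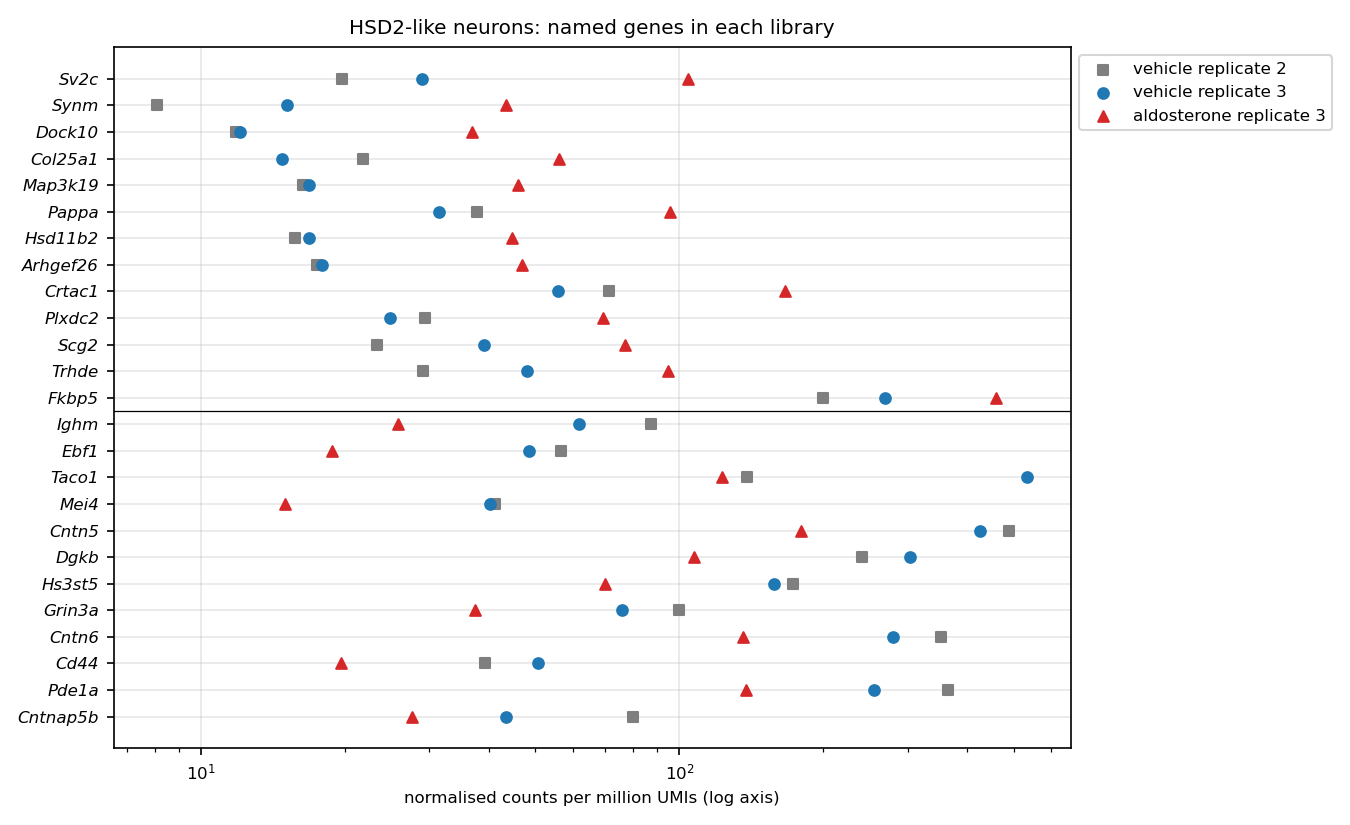
Normalised level (CPM) of named genes in HSD2-like neurons on a log axis, with 1 point per library (squares, vehicle replicate 2; circles, vehicle replicate 3; triangles, aldosterone replicate 3). Sv2c stood at 19.7 and 29.0 CPM with vehicle and 104 CPM with aldosterone, and Cntn5 at 488, 426 and 179 CPM, while Taco1 differed most between the vehicle libraries.

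Several genes fixed in advance as hormone receptors or targets did not pass the test in HSD2-like neurons. Nr3c2, the mineralocorticoid receptor, stood at 2668 and 3131 CPM with vehicle and 3298 CPM with aldosterone (log2 0.19, adjusted p = 0.283, 0.08 within replicate 3), and Nr3c1, the glucocorticoid receptor, had a log2 fold change of -0.37 (adjusted p = 0.223, -0.38 within replicate 3). Sgk1, a kinase induced by aldosterone in kidney, had 44.3 and 34.9 CPM with vehicle and 45.4 CPM with aldosterone (log2 0.19, SE 0.19, adjusted p = 0.747, 0.38 within replicate 3). Agtr1a had a log2 fold change of 0.06 (adjusted p = 0.923, 0.31 within replicate 3) and of -0.15 without vehicle replicate 3. Per1 stood at log2 0.59 (adjusted p = 0.359, 0.72 within replicate 3) and Tsc22d3 at 0.93 (adjusted p = 0.654, 0.85), from 1.94 and 1.83 CPM to 3.61 CPM. The activity marker Fos was near the limit of detection at 0.485 and 1.46 CPM with vehicle and 3.87 CPM with aldosterone (log2 2.00, SE 0.83, adjusted p = 0.205, 1.20 within replicate 3). Scnn1a, a subunit of the epithelial sodium channel, had 5, 4 and 1 UMIs in the 3 libraries and was not tested.

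Of the 30 listed mineralocorticoid and glucocorticoid receptor targets, 20 were tested in HSD2-like neurons and 4 rose, with 16 not past the test. Besides Fkbp5 these were Errfi1, a feedback inhibitor of growth factor receptors (log2 1.23, adjusted p = 3.24e-07), Tiparp (1.07, adjusted p = 0.0271) and the transcription factor gene Zbtb16 (0.35, SE 0.11, adjusted p = 0.0429, 0.20 within replicate 3). In the alternatives in which Zbtb16 lost its call, its adjusted p ran from 0.0577 to 0.679. Adjusted over the list alone, 5 rose and none fell, the fifth being Glul at log2 0.91. The median log2 fold change of the list was 0.48, with a camera adjusted p = 1.61e-05 and an adjusted p = 0.743 with an estimated correlation. Within replicate 3 its median of 0.58 lay at percentile 100 of matched random lists.

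The epithelial sodium transport list had no gene past the test among 9 tested (camera adjusted p = 0.964, 0.970 with an estimated correlation). Adjusted over the list alone, 1 was higher and 2 were lower, Nedd4l and Stk39 (log2 -0.36 and -0.42). The median of this list was 0.19 while its mean was -0.0033 and the test pointed down. Of 13 tested steroid receptors and cofactors, Hsd11b2 rose and 12 did not pass, with 1 also adjusted over the list alone (camera adjusted p = 0.106, 0.743 with an estimated correlation). Of 20 tested genes of synaptic vesicles and release, Sv2c and the active zone gene Rims1 (log2 0.37, adjusted p = 0.00333) rose, and the same number, 2, passed adjusted over the list alone (camera adjusted p = 0.247, 0.743 with an estimated correlation).

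Among 39 neuronal ion channels and pumps, 2 rose and 4 fell. The cation channel genes Trpc5 (log2 1.09, adjusted p = 1.02e-06, 1.13 within replicate 3) and Trpc4 (1.01, adjusted p = 3.75e-05) rose. Those that fell included the potassium channel genes Kcnq3 (-0.99, adjusted p = 1.84e-11) and Kcnh7 (-0.39, adjusted p = 0.0117) and the cation channel gene Trpm3 (-0.66, adjusted p = 0.000135). Adjusted over the list alone the numbers were 2 and 8 (camera adjusted p = 0.838, 0.927 with an estimated correlation), with a median of 0.0024 and a mean of -0.01. Of 11 tested activity-dependent genes, the neurotrophin gene Bdnf rose from 11.8 and 11.5 CPM to 25.5 CPM (log2 1.13, adjusted p = 0.00125), alone also when adjusted over the list alone. The median of this list was 0.51 (camera adjusted p = 0.000264, and adjusted p = 0.743 with an estimated correlation), and its median of 0.49 within replicate 3 lay at percentile 99.4.

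Of 18 tested circadian clock genes, Rorb rose (log2 1.63, adjusted p = 2.52e-06) from 4.04 and 12.0 CPM to 24.5 CPM, and Rora (-0.49, adjusted p = 0.000149) and Per3 (-0.53, adjusted p = 0.0115) fell. Adjusted over the list alone 1 rose and 4 fell (camera adjusted p = 0.270, 0.743 with an estimated correlation). Neither the 8 tested neuropeptides nor the 7 tested peptide and hormone receptors held a gene past the test, nor did they when adjusted over the list alone. Their camera adjusted p-values were 0.176 and 0.661 (0.743 and 0.859 with an estimated correlation). The prodynorphin gene Pdyn stood at 5.99, 1.28 and 1.03 CPM, and Lepr, the leptin receptor, at a log2 fold change of 0.26.

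Of 10 tested genes of the unfolded protein and integrated stress response none passed, also adjusted over the list alone (camera adjusted p = 0.270, 0.837 with an estimated correlation). Of 7 heat shock genes, the chaperones Hspa8 (log2 0.63, adjusted p = 0.0125) and Hsp90aa1 (0.53, adjusted p = 0.0168) rose, 3 adjusted over the list alone (camera adjusted p = 0.270, 0.743 with an estimated correlation). The list of 16 cholesterol synthesis genes did not pass as a set (camera adjusted p = 0.610, 0.939 with an estimated correlation). None of 20 tested nuclear-encoded genes of oxidative phosphorylation passed, also adjusted over the list alone, while their median was 0.30 (camera adjusted p = 4e-04, and adjusted p = 0.743 with an estimated correlation) and lay at percentile 99.9 within replicate 3. Of 12 tested mitochondrially encoded RNAs none passed, also adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.276, 0.859 with an estimated correlation), and within replicate 3 their median of 0.49 lay at percentile 99.87.

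Markers of other cell types moved in the HSD2-like sums as well. Of 11 tested myelin genes, 2 rose, among them Enpp2 by log2 0.60 (adjusted p = 0.00526), with 7 higher when adjusted over the list alone. The median of the list was 0.83 (camera adjusted p = 9.85e-06, and adjusted p = 0.743 with an estimated correlation), and its median within replicate 3 of 0.67 lay at percentile 99.97. Of oligodendrocyte genes outside that list, chosen after their values were seen, Bcas1 rose from 1.94 and 3.47 CPM (log2 3.22, adjusted p = 3.52e-17, 2.72 within replicate 3) and St18 from 10.5 and 12.8 CPM to 34.8 CPM (1.58, adjusted p = 2.15e-08, 1.42). Of 8 tested reactive astrocyte genes Cd44 fell, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.270, 0.743 with an estimated correlation). None of 8 microglial genes passed, 1 adjusted over the list alone (camera adjusted p = 0.270, 0.837 with an estimated correlation). The list of 12 interferon response genes did not pass as a set (camera adjusted p = 0.247, 0.837 with an estimated correlation). In the X inactivation and Y-linked list, Xist was called higher and Uty and Kdm5d lower, with 1 and 3 adjusted over the list alone (camera adjusted p = 0.600, 0.837 with an estimated correlation).

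The change in HSD2-like neurons differed from that in other neurons for many of these genes. Sv2c rose in HSD2-like neurons and stood at 109, 95.7 and 98.9 CPM in other neurons of vehicle replicate 2, vehicle replicate 3 and aldosterone replicate 3, a difference of the log2 effects of 2.19 (SE 0.16, adjusted p = 1.06e-25). Crtac1 differed by 1.62 (adjusted p = 5.41e-20), Dock10 by 1.66 (adjusted p = 3.99e-12), Col25a1 by 1.53 (adjusted p = 8.26e-13) and Synm by 1.64 (adjusted p = 0.000124). Hsd11b2 differed by 3.21 (SE 0.72, adjusted p = 0.00184), where other neurons had 13, 12 and 4 UMIs. These 6 genes were chosen after it was seen that the rule fixed in advance took genes with a group at 0 UMIs.

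The class by treatment term passed for 316 of 18755 genes, 203 with a more positive and 113 with a more negative effect in HSD2-like neurons, and 1675 had an unadjusted p under 0.05. Of the 516 genes called in HSD2-like neurons, 241 passed this test. Over 514 of them the median log2 fold change in the direction of the call was 0.76 in HSD2-like neurons and 0.14 in other neurons. Against the class named glutamatergic alone the term passed for 91 genes, and against GABAergic or glycinergic neurons alone for 141.

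**Figure D2:**
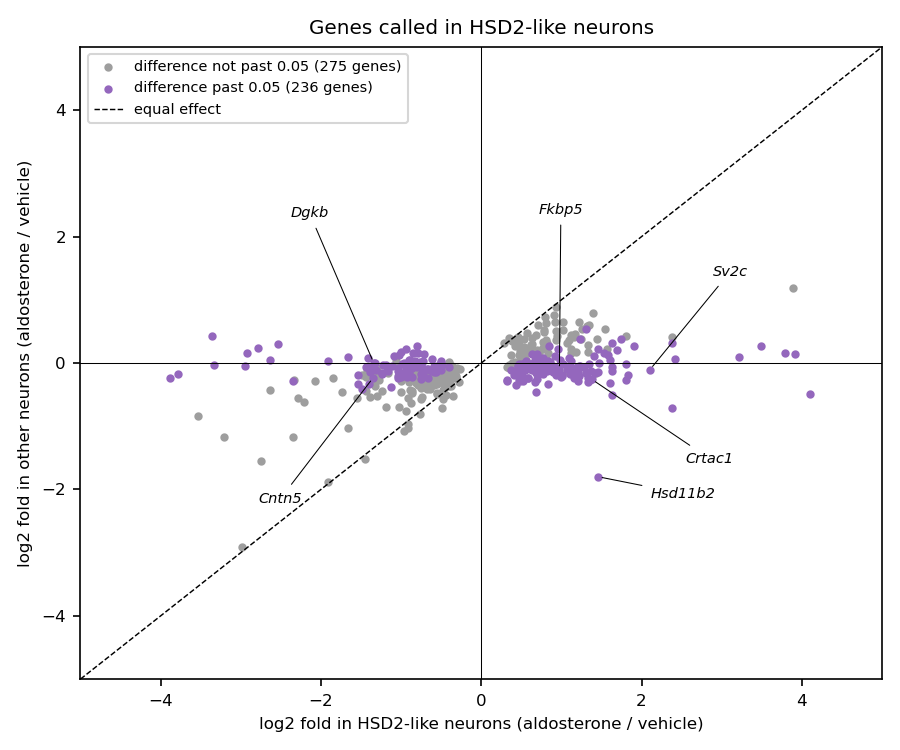
Log2 fold change (aldosterone over vehicle) of genes called in HSD2-like neurons, in HSD2-like neurons on the horizontal axis and in other neurons on the vertical axis, with 1 point per gene, purple where the difference passed an adjusted p of 0.05, and without genes that had a treatment group at 0 UMIs in HSD2-like neurons. Sv2c is at 2.11 in HSD2-like neurons and near 0 in other neurons, and Hsd11b2 at 1.46 and -1.80.

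In other neurons together, the genes fixed in advance had log2 fold changes of -0.11 for Fkbp5 (adjusted p = 0.780, -0.18 within replicate 3), -0.03 for Zbtb16 (adjusted p = 0.942, -0.09), -0.02 for Sgk1 (adjusted p = 0.968, 0.09) and 0.36 for Tsc22d3 (adjusted p = 0.650, 0.25). edgeR called 0 of 19536 genes, with 1978 at an unadjusted p under 0.05, and the DESeq2 Wald test called 17. Without the low-count filter edgeR did call genes in this class, as given below. In GABAergic or glycinergic neurons 80 genes rose and 105 fell of 17650. The imprinted gene Nap1l5 rose from 66.4 and 74.0 CPM to 118 CPM (log2 0.76, adjusted p = 4.68e-05, 0.68 within replicate 3), and Rnf227 (0.88, adjusted p = 0.000717, 0.81), Tceal5 (0.73, adjusted p = 0.00355, 0.74), Fam173a (0.72, adjusted p = 0.00259, 0.64) and the histone gene H3f3b (0.68, adjusted p = 0.00114, 0.57) rose. The transcription factor genes Maf (-1.13, adjusted p = 4.85e-06, -1.11) and Foxp2 (-0.81, adjusted p = 0.000145, -0.93), the extracellular matrix gene Reln (-0.72, adjusted p = 0.000531, -0.78), the splicing regulator Rbm20 (-0.68, adjusted p = 0.00355, -0.65) and Taco1 (-1.52, adjusted p = 0.000568, -2.06) were lower. The cluster of this class with Maf and Rbm20 among its leading genes held 50 of 734, 35 of 598 and 34 of 952 nuclei in vehicle replicate 2, vehicle replicate 3 and aldosterone replicate 3. By the DESeq2 Wald test 12 genes were called in this class, and 0 passed with sums thinned to equal totals.

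In cholinergic neurons 3 genes rose and 3 fell. The class joined a shallower and a deeper cluster, at medians of 14158 and 97364 UMIs. Its deeper cluster held 8 of 99, 9 of 61 and 12 of 68 nuclei in vehicle replicate 2, vehicle replicate 3 and aldosterone replicate 3. With vehicle replicate 2 set against the other pair, more genes were called in this class than with the aldosterone library. The sorting receptor gene Sorcs1 rose (log2 1.24, adjusted p = 0.0150, 1.08 within replicate 3), as did Zfp804b (1.17, adjusted p = 0.0234, 1.27). The glutamate receptor gene Grm8 (-1.13, adjusted p = 0.0344, -1.08), the glycosyltransferase gene Galnt18 (-1.09, adjusted p = 0.0367, -1.01) and Tafa1 (-1.08, adjusted p = 0.0415, -0.97) fell. The DESeq2 Wald test called 0 genes there, where 436 reached an unadjusted p under 0.05 in edgeR. The class named glutamatergic held 239 nuclei, and further neurons with Slc17a6 lay in clusters without 3 markers, which entered other neurons only. No gene was called by edgeR in that class (518 at an unadjusted p under 0.05, and 0 by DESeq2) or in catecholaminergic neurons (845 at an unadjusted p under 0.05). Without the low-count filter, and with thinned sums, edgeR did call genes in both classes, as given below. Fkbp5 stood at log2 -0.35 in glutamatergic (-0.50 within replicate 3), -0.25 in cholinergic (-0.27) and -0.11 in catecholaminergic neurons (0.12), with adjusted p-values of 0.911, 1 and 0.943.

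In astrocytes 9 genes rose and 33 fell. The guanylate-binding protein gene Gbp5, a target of interferon, rose from 14.0 and 17.2 CPM to 43.5 CPM (log2 1.49, adjusted p = 0.000651, 1.32 within replicate 3), and Scg2 (1.14, adjusted p = 0.00982, 1.17), the synaptic adhesion gene Lrrtm4 (0.92, adjusted p = 0.0284, 0.57), Edil3 (0.86, adjusted p = 0.0273, 0.69) and the glycolytic gene Gapdh (0.78, adjusted p = 0.0482, 0.85) also rose. The phosphodiesterase gene Pde3a fell from 59.8 and 38.7 CPM to 12.4 CPM (log2 -2.01, adjusted p = 0.000192, -1.62), with Vwa3b (-1.17, adjusted p = 0.0273, -0.77), the metalloprotease gene Adam12 (-1.14, adjusted p = 0.0273, -0.95), the matrix gene Tnc (-1.14, adjusted p = 0.0102, -1.19) and Anxa3 (-1.08, adjusted p = 0.0497, -1.04). The interferon response list had a median of -0.04 in astrocytes (camera adjusted p = 0.914, 0.948 with an estimated correlation). Of the neuron markers in the astrocyte sums, Syt1 stood at log2 0.48, Stmn2 at 0.45, Grin1 at 0.36 and Snap25 at 0.08 over vehicle. Snhg11 stood at -0.08, Meg3 at -0.23, Rbfox3 at -0.365 and Rbfox1 at -0.99, all without a test. With the DESeq2 Wald test 5 genes were called in astrocytes, and 1 passed with thinned sums.

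In oligodendrocytes 6 genes rose and 2 fell, among them H3f3b (log2 1.06, adjusted p = 0.0346, 0.96 within replicate 3) and the sodium pump subunit gene Atp1b1 (1.04, adjusted p = 0.0346, 1.10), which rose, and Hmga2, a chromatin protein gene that fell from 247 and 237 CPM to 64.4 CPM (-1.91, adjusted p = 2.72e-05, -1.87). The DESeq2 Wald test called 4 genes there and edgeR without the low-count filter 63. In oligodendrocyte precursors 35 genes rose and 29 fell. Among them Snx15 (log2 1.76, adjusted p = 0.000599, 1.31 within replicate 3), the interferon-inducible GTPase gene Iigp1 (1.66, adjusted p = 0.000581, 1.30), Eid1 (1.65, adjusted p = 0.00121, 1.48) and Scoc (1.62, adjusted p = 0.0258, 1.75) rose. Grm8 (-2.38, adjusted p = 0.000222, -2.64), Irak2 (-1.84, adjusted p = 0.0383, -1.83), Fras1 (-1.72, adjusted p = 0.0379, -1.99), L3mbtl3 (-1.63, adjusted p = 0.0355, -1.33) and Myo1e (-2.53, adjusted p = 0.000497, -3.15), at 13.3 and 67.4 CPM with vehicle, were lower. In the precursors DESeq2 called 1 gene.

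Microglia had no called gene by edgeR, with 620 at an unadjusted p under 0.05, though edgeR called 46 without the low-count filter. Fkbp5 stood at 147 and 119 CPM with vehicle and 223 CPM with aldosterone (log2 0.73, adjusted p = 0.765, 0.90 within replicate 3), and Tsc22d3, a glucocorticoid-induced gene, at 25.9, 16.4 and 37.4 CPM. The receptor target list had a median of 0.52 in microglia (camera adjusted p = 0.00462, and adjusted p = 0.736 with an estimated correlation). In oligodendrocytes Fkbp5 stood at log2 0.79 (adjusted p = 0.360, 0.71 within replicate 3) and in astrocytes at 0.18 (adjusted p = 0.872, 0.14). Choroid plexus had no called gene (311 at an unadjusted p under 0.05, 38 called without the filter), with Sgk1 at 400, 345 and 228 CPM.

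In ependymal cells 23 genes rose and 12 fell. The increases included Penk, which encodes proenkephalin and also led the shallow unnamed cluster (log2 2.15, adjusted p = 0.00375, 2.10 within replicate 3), Cntnap5b (2.37, adjusted p = 0.000558, 1.86), Dgkh (2.19, adjusted p = 0.0184, 2.24), Ryr3 (2.01, adjusted p = 0.00037, 1.56) and the glutamate receptor gene Grik1 (2.07, adjusted p = 0.00037, 1.20), at 12.6 and 50.5 CPM with vehicle. With a minimum of 1000 genes per nucleus Grik1 turned to -0.59. Of the neuron markers in these sums, Stmn2 stood at log2 0.74, Snap25 at 0.64, Rbfox3 at 0.63, Grin1 at 0.53 and Syt1 at 0.48 over vehicle, Snhg11 at 0.14, and Rbfox1 at -0.13 and Meg3 at -0.54, without a test. Hs3st3b1 (-2.81, adjusted p = 0.00834, -2.61), Rasgrf2 (-2.32, adjusted p = 0.000153, -2.32), Rbm20 (-2.16, adjusted p = 0.00695, -2.37), Taco1 (-1.99, adjusted p = 0.000221, -2.67) and the chloride channel gene Ano1 (-1.94, adjusted p = 0.00779, -2.01) were lower. In this class DESeq2 called 0 genes, where 725 reached an unadjusted p under 0.05 in edgeR.

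In leptomeningeal cells, with 46 nuclei in the aldosterone library, 57 genes rose and 61 fell. The neuronal adhesion gene Cntn5 rose from 25.3 and 97.7 CPM to 613 CPM (log2 3.49, adjusted p = 1.07e-12, 2.58 within replicate 3), and Tafa2 (3.38, adjusted p = 7.99e-10, 3.12), Ndnf (3.94, adjusted p = 8.1e-06, 4.90), Aplp1 (3.12, adjusted p = 0.0371, 3.06) and Mageb18 (3.10, adjusted p = 0.0373, 4.28) rose. The transporter genes Slc9a2, Slc2a12 and Slc26a7 had 138 and 163, 70.8 and 195, and 164 and 65.1 CPM with vehicle and 0 with aldosterone, as had Afap1l1 from 155 and 77.3 CPM and Baiap2l1 from 91.0 and 81.4 CPM. A count of 0 allows up to 19.7 CPM in this sum. Of neuron markers, Syt1 stood there at 113, 177 and 381 CPM, Stmn2 at 27.5, 18.4 and 52.6 CPM and Rbfox1 at 519, 847 and 756 CPM, without a test. In leukocytes 39 genes rose and 28 fell. Dach1 (4.27, adjusted p = 0.00681, 3.31), the glutamate receptor gene Grik3 (3.75, adjusted p = 0.00739, 2.67), Klra7 (3.72, adjusted p = 6.79e-05, 2.56), Reln (3.63, adjusted p = 2.21e-05, 2.72) and Rgs6 (3.60, adjusted p = 3.03e-05, 3.77) rose. Mitochondrially encoded RNA had a median log2 fold change of 1.34 in leukocytes (1.49 within replicate 3), and the neuron markers Snap25 and Rbfox1 stood there at 92.8, 394 and 320 CPM and at 160, 320 and 596 CPM. The costimulatory gene Cd86 fell from 205 and 347 CPM to 12.3 CPM (-4.36, adjusted p = 4.72e-06, -4.17), with Prickle1 (-4.26, adjusted p = 0.00421, -3.77) and Cd40lg (-4.15, adjusted p = 0.00893, -3.45), and Tox2 had 143 and 75.1 CPM with vehicle and 0 with aldosterone, which allows up to 16.3 CPM. The DESeq2 Wald test called 3 genes in leptomeningeal cells and 1 in leukocytes, and these classes held 152161 and 184502 UMIs in the aldosterone library.

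Some gene lists passed camera at the preset correlation in the same direction in several classes. Nuclear-encoded oxidative phosphorylation genes had a positive median in all 15 sums tested, from 0.21 to 0.53, and passed camera upward in 13. Myelin genes passed upward in 8 of 15, neuropeptides in 7 of 12 and interferon response genes in 5 of 15, and ion channels passed downward in 5 of 15. Medians of myelin genes and neuropeptides were above 0 in every class tested. Those of interferon response genes ran from -0.26 to 1.39 and those of ion channels from -0.30 to 0.16, so both lists went either way. In other neurons the oxidative phosphorylation median was 0.38 (camera adjusted p = 3.91e-07, and adjusted p = 0.815 with an estimated correlation). Over 272 pairs of list and class, 58 passed at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.696. The latter test rests on 1 residual degree of freedom, so its lack of passing lists decides nothing about them. The passes at the preset correlation rest on the spread across genes, so they describe this 1 aldosterone library only. In the sum of all nuclei edgeR called 0 of 21753 genes, with 1270 at an unadjusted p under 0.05 and 5 called without the filter, and Fkbp5 stood at log2 0.18 (adjusted p = 0.856, 0.03 within replicate 3).

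When each library in turn was set against the other pair in HSD2-like neurons, vehicle replicate 2 alone gave 8 genes and vehicle replicate 3 alone 7, against 516 for the aldosterone library. With a vehicle library alone, the aldosterone library is in the pair that sets the spread, so a difference of that library can lower such counts. The counts of the 3 choices are thus not like for like. In most other classes, among them cholinergic neurons, and in the sum of all nuclei a vehicle library gave more genes than the aldosterone library. In astrocytes vehicle replicate 2 alone gave 148 genes and the aldosterone library 42, in other neurons the numbers were 65 and 0, in oligodendrocytes 95 and 8, in ependymal cells 111 and 35, and in microglia vehicle replicate 3 alone gave 60. In GABAergic or glycinergic neurons vehicle replicate 2 alone gave 77 and the aldosterone library 185, and in oligodendrocyte precursors vehicle replicate 3 alone gave 35 and the aldosterone library 64.

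**Figure D3:**
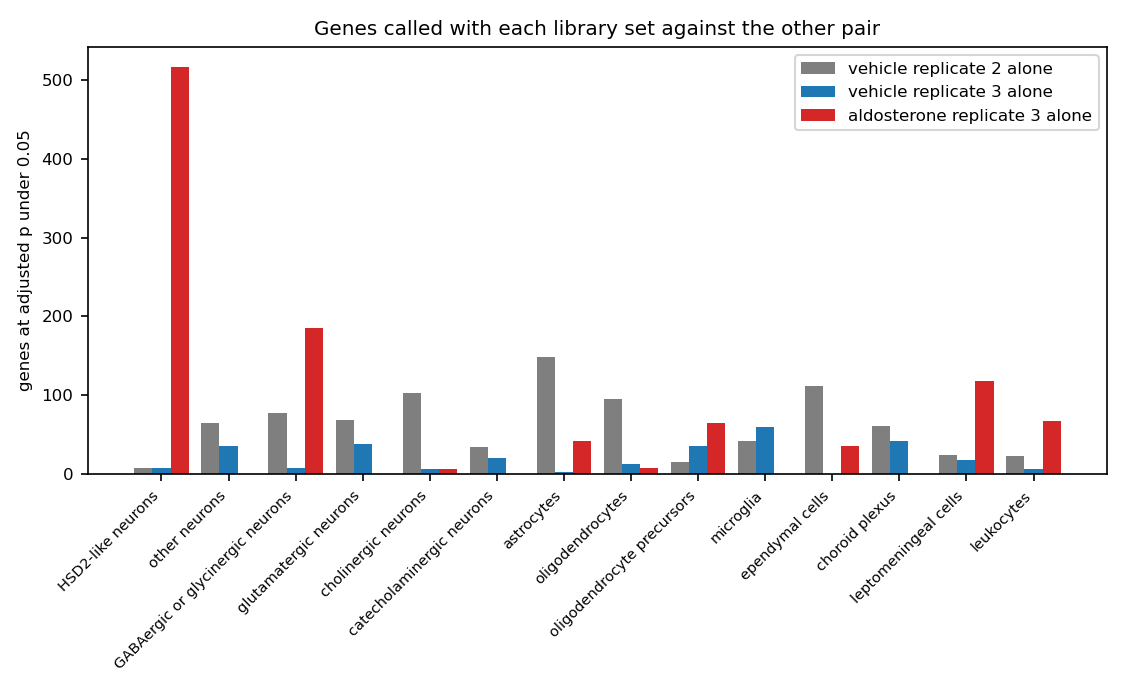
Genes at an adjusted p under 0.05 (vertical axis) when each library in turn is set against the other pair, for each class, with 1 bar per lone library. In HSD2-like neurons the bars stand at 8, 7 and 516 genes, and in astrocytes at 148, 3 and 42.

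The libraries also differed in transcripts of the sex chromosomes, in pools that the labels give as of mixed sex. Xist, the transcript of the inactive X chromosome, stood at 177, 25.2 and 194 CPM in HSD2-like neurons of vehicle replicate 2, vehicle replicate 3 and aldosterone replicate 3, and the Y-linked gene Uty at 120, 220 and 92.6 CPM. Both were called between treatments (adjusted p = 7.28e-10 and 1.71e-07). The choroid plexus went the other way, with Xist at 325, 887 and 782 CPM and Uty at 210, 46.4 and 141 CPM.

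**Figure D4:**
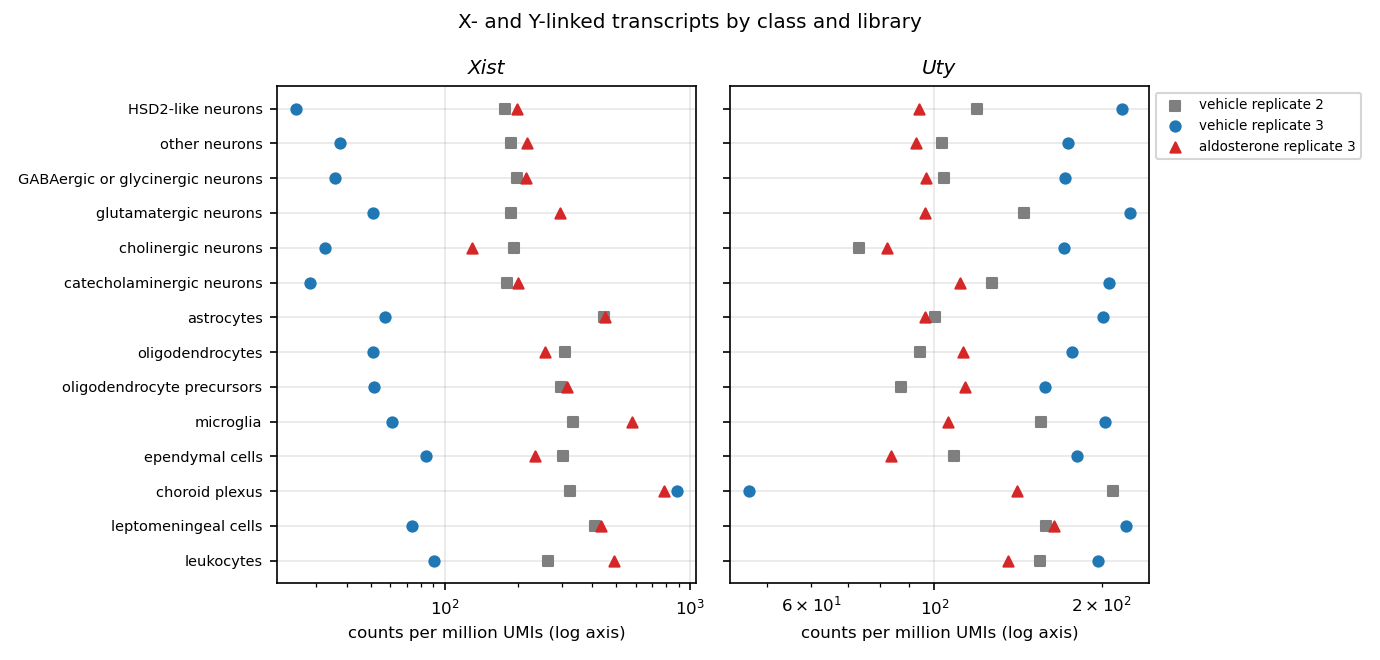
Level (CPM, log axis) of the X-linked transcript Xist and the Y-linked gene Uty in each class, with 1 point per library. Xist is lowest in vehicle replicate 3 in every class shown but the choroid plexus, where it stands at 887 CPM in that library.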

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

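The tests chosen only after the result was seen were those of the sequencing instruments, a shift of the whole library, the sex mixture, the depth of the sums and per nucleus, the choice of the lone library and cytoplasmic RNA, the difference from GABAergic or glycinergic neurons alone, and the naming of Hsd11b2, Sv2c, Dock10, Synm, Crtac1 and Col25a1 for the difference between classes.

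By the class by treatment term, the difference of the aldosterone library from the vehicle libraries was not the same in HSD2-like and other neurons for 316 genes. Hsd11b2 differed by log2 3.21, Sv2c by 2.19, Dock10 by 1.66, Synm by 1.64, Crtac1 by 1.62 and Col25a1 by 1.53, each more positive in HSD2-like neurons. For Hsd11b2 a log2 fold change of -1.80 in other neurons (adjusted p = 0.523), from 13, 12 and 4 UMIs, made up more of the difference than that in HSD2-like neurons. Against the class named glutamatergic alone Hsd11b2 (0.61, adjusted p = 0.998) and Synm (0.94, adjusted p = 0.960) lost the call. Against GABAergic or glycinergic neurons alone they lost it too (adjusted p = 0.372 and 0.0723), though at differences of 2.745 and 1.66, near those against all other neurons. Sv2c, Dock10, Crtac1 and Col25a1 kept the call in both. In other neurons of vehicle replicate 2, vehicle replicate 3 and aldosterone replicate 3 the levels were 199, 184 and 192 CPM for Dock10, 216, 204 and 227 CPM for Col25a1, and 3.63, 3.57 and 4.53 CPM for Synm.

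The 6 largest fitted differences were of genes with a treatment group at 0 UMIs in HSD2-like neurons, and are given as bounds with the group at 0 set to 3 counts. Qrfpr, the receptor of the neuropeptide QRFP, had 17, 43 and 0 UMIs in HSD2-like neurons of vehicle replicate 2, vehicle replicate 3 and aldosterone replicate 3, so that the log2 effect was lower than in other neurons with a bound of -2.30, and of -1.63 against vehicle replicate 2 alone. The bound was -1.72 for Frzb (15, 11 and 0 UMIs) and -1.57 for Ccdc18 (20, 15 and 0). The values of -2.08 for Fer1l6 (3, 33 and 0 UMIs) and -1.92 for Pkhd1l1 (12, 2 and 0) each rest on 1 vehicle library, since the other, at 0.482 CPM of Fer1l6 in vehicle replicate 2 and 0.36 CPM of Pkhd1l1 in vehicle replicate 3, lay below the level of 3 counts in the aldosterone sum. For Pkhd1l1 the part from HSD2-like neurons was -0.60, and other neurons had 49, 66 and 156 UMIs (log2 1.31). Fam129a had 0, 0 and 7 UMIs, with a bound of 3.42, and of 2.52 and 2.30 against vehicle replicate 2 and vehicle replicate 3 alone. Against GABAergic or glycinergic neurons alone only Fam129a of these 6 kept the call (adjusted p = 0.0489), while the others kept their direction.

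The first pattern weighed is the 516 genes called in HSD2-like neurons of the aldosterone library. A difference between sequencing instruments would leave little within replicate 3. The median log2 fold change there, signed by the call, was 0.66 (quartiles 0.48 and 1.05), which argues against it as the whole cause. A sex mixture that separates vehicle replicate 3 was argued against as the whole cause by a signed median of 0.79 (quartiles 0.54 and 1.20) over vehicle replicate 2. The genes were chosen by their fold against both vehicle libraries, which raises both medians. In HSD2-like neurons Uty was lowest in the aldosterone library, so a part from sex mixture stays open. A shift shared by the library's other neurons was argued against as the whole cause by their signed median, at a ratio of 0.181 to that in HSD2-like neurons over genes chosen for their HSD2-like effect, but 71.0% of these genes had the same sign there, so a partly shared shift stays open. With sums thinned to the smallest total, that of the aldosterone library, 410 of 516 genes stayed called. Thinning leaves expected levels in CPM unchanged, so this shows only that most calls did not need the larger vehicle sums. Depth per nucleus was argued against by a signed median of 0.68 (quartiles 0.45 and 1.08) with nuclei matched on UMIs. The 3 choices of the lone library, of which 1 gave as many genes (516 against 8 for the highest other), are too few for a share under 0.05. These 3 choices are also not like for like, since with a vehicle library alone the aldosterone library enters the spread. The preparation of the 1 aldosterone pool cannot be told apart from its treatment. An effect of aldosterone therefore stays a hypothesis, with handling or animal differences of that pool as open explanations. Markers of other cell types also moved in the HSD2-like sums, and RNA or nuclei of other cells in these sums were not tested as a cause.

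The second pattern is the higher median of nuclear-encoded oxidative phosphorylation genes across classes of the aldosterone library. If more cytoplasm had come along with the nuclei, mitochondrially encoded RNA may be higher too, but its median was above 0.2 in 2 of 14 classes and at or below 0 in 7, while within replicate 3 it was above 0.2 in 10 and at or below 0 in 1, with 0.49 in HSD2-like neurons and 0.40 in astrocytes. The 7 met the number set against the explanation and the 10 the number set for it, and since the classes share their libraries and overlap, the explanation was settled as open after these values were seen, having first been read as excluded. Free RNA from neurons could also carry such transcripts into glia, where neuron markers had a median log2 fold change of 0.106 (quartiles -0.25 and 0.49, 40 values) against 0.50 for the oxidative phosphorylation list, above 0 and below the level it predicts. These markers did not move together, since Stmn2 and Snap25 stood above vehicle in each of the glial and ependymal classes, and Rbfox1 and Meg3 below. Both explanations stay open, and so does an effect of aldosterone, which was not tested apart from the library.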

How the results depend on the processing

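The tests chosen only after the result was seen were limma voom, the robust prior, the clustering without HSD2 markers and called genes, the deeper HSD2-like cluster alone, nuclei matched on UMIs, the genes beyond the gap between vehicle libraries and the difference from GABAergic or glycinergic neurons. The HSD2-like count was 516 and stayed within 1.5 times of it, from 388 to 517, with DESeq2 size factors, no filter, a minimum of 1000 or of 300 genes, thinned sums, nuclei with an Hsd11b2 UMI, a robust prior and the clustering without markers and called genes (388, of which 365 shared). Resolution 0.5 gave HSD2-like clusters of the same sizes and marker levels as the main clustering. Its count and the values of named genes below were thus kept by construction. The genes beyond the vehicle gap (436) are a part of the 516 and not a rerun. The count was 74 with the DESeq2 Wald test (all 74 shared), 276 with limma voom (276 shared, 57.2% of them higher against 46.9%), 291 in the deeper cluster alone (290 shared), 321 with Scrublet calls kept in (321 shared), 330 at resolution 2.0 (327 shared) and 239 with nuclei matched on UMIs (208 shared), where only 78 nuclei per library entered. The cause was not tested. Of 492 values of genes named in HSD2-like neurons over the alternatives with a test, 465 kept direction and side of the threshold, 26 kept direction and lost the call, 1 gained it and 0 turned. In other classes these numbers were 569, 197 and 1 of 777, with 10 turned, and for genes of the difference 19 of 33 were kept and 14 lost.

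No paired analysis was possible because the libraries analysed share only 1 replicate number, 3, between treatments. Leaving out a vehicle library left no residual degree of freedom, so these runs gave values without a test for named genes and no counts. Of 66 such values in HSD2-like neurons 1 had the other sign, that of Agtr1a, and 8 moved by more than the SD between the vehicle libraries. In other classes 20 of 230 had the other sign and 44 moved by more than that SD. By arithmetic, leaving out 1 of 2 vehicle libraries mostly moves a value by less than this SD. The counts of 8 and 44 thus say little about stability. None of the 1 and 20 was of a gene that had been called. The naming rule largely fixed this, since it took called genes only outside the range of both vehicle libraries. The leptomeningeal and leukocyte sums of the aldosterone library held 152161 and 184502 UMIs, where a count of 0 allows up to 19.7 and 16.3 CPM, and the simulated test in microglia recovered 17 of 200 genes at a fold of 2.

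The difference between HSD2-like and other neurons passed for 315 genes with DESeq2 size factors (280 shared), 91 against the class named glutamatergic only (73 shared) and 141 against GABAergic or glycinergic neurons only (138 shared), where fewer nuclei entered. With an estimated correlation the adjusted p of the receptor target, activity, myelin and oxidative phosphorylation lists in HSD2-like neurons was 0.743 each, and 0 pairs of list and class passed. On 1 residual degree of freedom that setting could hardly pass a list, so it decides nothing about these lists. With 1000 or more genes the HSD2-like share was 3.52%, 5% and 3.65% in vehicle replicate 2, vehicle replicate 3 and aldosterone replicate 3.

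The counts of the other classes were less stable, and the cause was not tested. Without the low-count filter they were 323 in other neurons, 357 in GABAergic or glycinergic, 23 in glutamatergic, 48 in cholinergic and 54 in catecholaminergic neurons, 180 in astrocytes, 63 in oligodendrocytes, 46 in microglia, 0 in ependymal cells, 38 in choroid plexus and 5 in all nuclei. With the DESeq2 Wald test they were 17 in other neurons, 12 in GABAergic or glycinergic and 0 in cholinergic neurons, 5 in astrocytes, 4 in oligodendrocytes, 1 in their precursors, 0 in ependymal cells, 3 in leptomeningeal cells and 1 in leukocytes. With DESeq2 size factors they were 186 in astrocytes, 15 in oligodendrocytes, 1 in microglia, 0 in ependymal cells and 11 in choroid plexus. With 1000 or more genes they were 48 in GABAergic or glycinergic neurons, 0 in astrocytes, 3 in oligodendrocytes, 39 in their precursors, 17 in microglia, 13 in ependymal cells, 74 in choroid plexus and 22 in leptomeningeal cells. With 300 or more genes and no mitochondrial filter they were 7 in astrocytes, 0 in oligodendrocytes, 1 in microglia and 9 in choroid plexus. With Scrublet calls kept in they were 406 in GABAergic or glycinergic, 1 in glutamatergic and 1 in catecholaminergic neurons, 1 in astrocytes, 19 in oligodendrocytes, 70 in microglia, 1 in ependymal cells, 13 in choroid plexus and 7 in leptomeningeal cells. With thinned sums they were 0 in GABAergic or glycinergic, 21 in glutamatergic and 66 in catecholaminergic neurons, 1 in astrocytes, 75 in oligodendrocytes, 36 in their precursors, 33 in microglia, 3 in ependymal cells and 31 in choroid plexus.

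Of the log2 fold changes that turned in alternatives with a test, Grik1 in ependymal cells had been called, and stood at -0.59 with 1000 or more genes. With that minimum Sgk1 in microglia was -0.087, Zbtb16 in ependymal cells -0.12 and Fkbp5 in leptomeningeal cells -0.36. Fkbp5 in leptomeningeal cells was also -0.075 without the filter, -0.040 with DESeq2 and -0.27 with Scrublet calls kept in, and in ependymal cells -0.059 with DESeq2. With thinned sums Zbtb16 was 0.00029 in other neurons and 0.13 in leptomeningeal cells. The cause was not tested.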

Other observations

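The genes named first here were chosen only after the result of their tests was seen, and no alternative was run for them, while the test of the hypothesis was written before its result.

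In HSD2-like neurons, Tafa1, which encodes a secreted protein of the brain, rose from 471 and 483 CPM with vehicle to 1113 CPM with aldosterone (log2 1.22, edgeR adjusted p = 6.39e-30). The cyclic nucleotide phosphodiesterase gene Pde10a rose from 1318 and 1365 CPM to 2694 CPM (log2 1.01, adjusted p = 7.13e-26), while Pde11a fell from 231 and 229 CPM to 166 CPM (log2 -0.47, adjusted p = 0.011). Slc9a3, a sodium and proton exchanger of kidney and gut, rose from 15.0 and 11.3 CPM to 33.3 CPM (log2 1.33, adjusted p = 5.09e-06), and the kinase gene Sgk3, a relative of Sgk1, from 6.47 and 9.49 CPM to 18.0 CPM (log2 1.18, adjusted p = 0.00649). Tafa1 fell in cholinergic neurons, from 333 and 288 CPM to 147 CPM, and the difference between these classes was not tested.

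Cxcl10, a chemokine induced by interferon, rose in astrocytes from 3.23 and 3.55 CPM to 28.3 CPM (log2 3.06, edgeR adjusted p = 1.09e-06), where the fixed interferon response list had a median of -0.04, a mean of -0.25 and a camera adjusted p = 0.914. Gbp5 rose in ependymal cells from 58.0 and 53.4 CPM to 145 CPM (log2 1.37, adjusted p = 0.0104), and Iigp1 in GABAergic or glycinergic neurons from 4.86 and 10.0 CPM to 17.4 CPM (log2 1.26, adjusted p = 0.00355). A cluster led by Gabra6 and Fat2, genes of cerebellar granule cells, held 172, 5 and 1 nuclei of vehicle replicate 2, vehicle replicate 3 and aldosterone replicate 3, with a median of 2702.5 UMIs, and was left out of the classes.

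The hypothesis was that aldosterone raises genes that already mark HSD2-like neurons, which would give higher genes a share of marking genes over 10 points above that of lower genes. The share at 2 times the level of other neurons in the vehicle libraries was 16.1% of higher genes (39), 24.1% of lower genes (66) and 4.13% of genes not called, a difference of -7.97 points. The vehicle level is also the denominator of the fold, which favours lower genes by construction, and with the levels of all libraries the shares were 25.2% and 18.6%, in the opposite order. The hypothesis stays open, which was settled after these values were seen.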
